A study of Mus musculus with 6 samples.

How the data were processed

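RNA from whole lenses of 2-day-old Balb/c mice was hybridised to Affymetrix arrays, 3 for transgenic and 3 for wild-type lenses, and each array was assigned to its genotype and replicate number by its title. Total RNA was extracted with a GenElute kit and biotin was introduced by in vitro transcription, per the labels' protocols. The deposited table held 1 log2 value per probe set and array. The summary and normalization methods the authors used before deposit are not given in the sources used here, and the scanner files were not used here. That the values were on a log2 scale was read from their range. The lowest value of the 6 arrays was 2.68 and the highest 14.8.

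The 64 control probe sets were set aside before normalization, which left 45037. A rule was set that arrays whose medians or quartiles differed by over 0.1 would be quantile normalised. The upper quartiles differed by 0.120, so quantile normalization in limma 3.58.1 (R 4.3.3) was applied. No 2 arrays held the same values. Probe sets were named from GEO's platform annotation, with symbols updated by gene identifier through the RefSeq table of GRCm38.p6, which matched 99.4% of probe sets with 1 symbol. In all, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none here. Each of 18193 genes was represented by the probe set with the highest mean over all 6 arrays among those with 1 symbol. For called genes named by the rule, the text gives other probe sets above the median level that went the other way or changed far less, and few of the dimmer ones. Among 299 called genes with a second probe set above the median level, 260 had a second probe set that moved in the same direction (87.0%). Of 4746 such genes that were not called, 61.1% did. The second probe set showed the larger part of the gene's log2 change in 176 of the 299 and in 2156 of the 4746. Differences of genes that were not called can be small, with signs left to noise, so the contrast in direction is a weak check. Files name no genome build, so no coordinates are given.

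Genotypes were compared with limma's linear model and empirical Bayes test (lmFit, eBayes) on log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The design holds 1 comparison, and the labels name no batch. The prior carried 3.80 degrees of freedom. Standard errors of changes are limma's moderated errors, and SDs are over 3 arrays. The genes named in the text follow a rule. It takes the 14 largest rises and 14 largest falls among genes past the threshold whose groups did not overlap and whose higher group reached the median of all probe sets, leaving out provisional symbols. It adds up to 4 members with the smallest p of each gene list (6 for lens lists), and 12 lens genes named in advance. Genes outside the rule are marked as such.

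The 36 gene lists cover lens fiber, epithelium and transcription factor genes, cytoskeleton, adhesion and matrix, cell cycle, stress, metabolism, signalling and markers of other cell types. They were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. In this test 10 lists passed, 2 upward and 8 downward. With an estimated correlation, none of the 36 passed. In limma's fry, which asks whether the genes of a list move on balance one way, 11 lists passed. A list score per array is the median over members of the difference from the member's mean over the 6 arrays.

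The fit was tested on simulated data: 5 sets of 6 arrays with the 18193 genes' own means and variances drawn from limma's prior distribution, 200 of the genes changed in each. For this comparison, 25.2% of genes changed by 0.5 on the log2 scale were recovered, 88.0% of those changed by 1, 99.6% of those changed by 2 and 100% of those changed by 3. Of all simulated calls 5.44% were false. Camera found 30 of 30 lists of 25 genes shifted by -0.4 and called 1 of 150 that were not shifted, with genes simulated as independent. In the real lists that passed, the estimated correlation ran from -0.00011 to 0.67. The simulated rate of false list calls therefore does not carry over to correlated lists.

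The rule for normalization, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. Those alternatives were the values as deposited, centring on a common median, leaving out dim probe sets, the mean of a gene's probe sets, every probe set on its own, trended robust variances, an ordinary test without moderation, array weights, a replicate block, each array left out, an added limit on the size of change and an estimated correlation. The neural retina score as a covariate, and list member counts without transgenic replicate 3, were chosen after seeing the data. Neighbouring genes were taken from the same RefSeq table.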

Results

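Transcript levels were measured in whole lenses of Balb/c mice at 2 days of age, in 3 transgenic and 3 wild-type samples, each hybridised to 1 Affymetrix array. After control probe sets were set aside, 45037 probe sets remained. The labels do not name the transgene. The design text gives 12 lenses for each genotype and 3 replicates, without saying whether the 12 lenses were shared among the replicates. Nothing states that the replicates came from separate animals, so the p-values measure only the spread between these 6 samples, which may be technical in part. The transgenic samples differed among themselves in Y-linked and skin transcripts, by the values given with the tissue markers, so they were not 1 pool of RNA. For short, the transgenic replicates are given as T1 to T3 and the wild-type replicates as W1 to W3. The deposited values lay on a log2 scale, with medians of 5.29 to 5.37 per array and highest values of 14.7 to 14.8. The number of arrays limits the precision of every value below. After quantile normalization the mean correlation of an array with the others of its group was 0.986 for transgenic replicate 3 and 0.990 to 0.994 for the other arrays.

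The comparison of the genotypes asks which transcripts of the newborn lens differ between transgenic and wild-type animals. Foxe3, which encodes a forkhead transcription factor of the lens epithelium, had the largest rise of all genes, 24.9-fold. Some genes of the maturing fiber cell fell, such as Bfsp1, which encodes the beaded filament protein filensin, and Dnase2b, which encodes the nuclease that clears DNA from fiber nuclei. The heme-degrading enzyme gene Hmox1 and the small heat shock protein gene Hspb1 also fell, while stress-induced Atf3 and Ddit3 rose. Of the crystallin genes, whose values lay near the top of the arrays' range, only Crygf passed. Of 18193 genes tested, 352 were higher and 475 lower in transgenic lenses (limma, adjusted p under 0.05). A log2 change of at least 1 was reached by 23 of the higher and 104 of the lower genes. When the deposited arrays were shifted to a common median instead of quantile normalised, 252 genes were higher and 666 lower.

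The counts were lower whichever array was left out, where the test also had fewer arrays to work with. Without transgenic replicate 1 they were 113 higher and 249 lower, and without transgenic replicate 2 they were 73 and 172. Without transgenic replicate 3, which carried transcripts of skin and muscle, they were 249 and 323. Without wild-type replicate 1 they were 178 and 390, without wild-type replicate 2 they were 70 and 153, and without wild-type replicate 3 they were 76 and 154. The groups did not overlap for 28.8% of genes, where chance gives 10% for 3 arrays against 3.

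**Figure D1:**
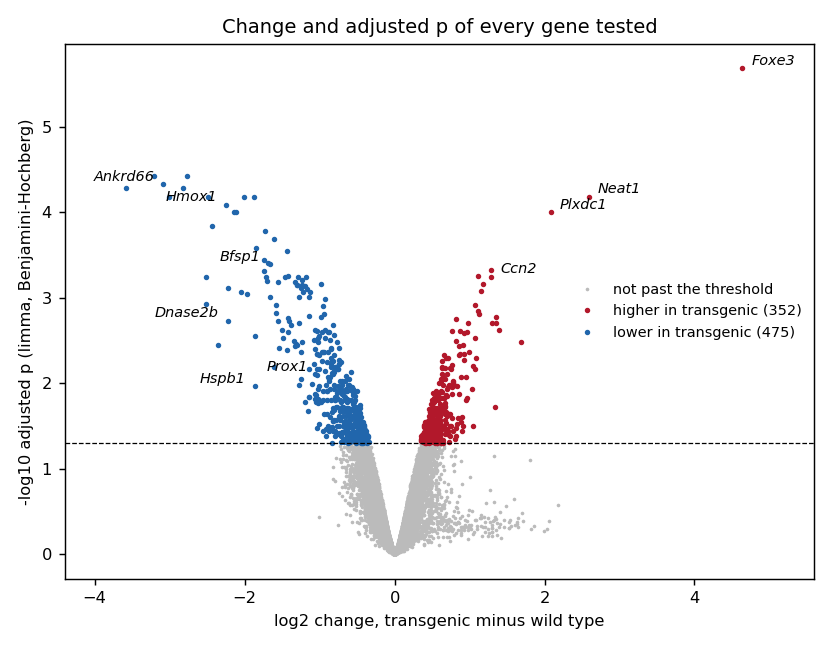
Each point is 1 of 18193 genes, with the log2 change (transgenic minus wild type) on the horizontal axis and the negative log10 of limma's adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05. Foxe3 lies apart at 4.64, and 104 genes lie at or below -1 past the threshold, against 23 at or above 1.

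Foxe3 stood at 13.38 ± 0.04 in transgenic and 8.74 ± 0.17 in wild-type lenses (log2 value, SD, n = 3 each), a rise of 4.64 ± 0.10 (SE; limma adjusted p = 2.07e-06). Foxe3 has a single probe set here. The next largest rises were far smaller. Neat1, the long noncoding RNA that builds paraspeckles, rose by 2.59 ± 0.12 (SE) and Plxdc1, which encodes a membrane protein with a plexin domain, by 2.08 ± 0.11. For both genes a second, dimmer probe set showed differences of 0.19 and 0.0031, respectively. Srpk3, encoding a kinase of splicing factors, rose by 1.68, Arfgef3 by 1.40, the decoy death receptor gene Tnfrsf23 by 1.36 and Tmem268 by 1.35. Chac1, whose product degrades glutathione, rose by 1.34, the phosphatase gene Dusp15 by 1.30, the matricellular growth factor gene Ccn2 by 1.29 and Wls, whose product carries Wnt proteins to the cell surface, by 1.29. Retreg1, encoding a receptor for endoplasmic reticulum autophagy, rose by 1.18, the calcium-binding protein gene S100a1 by 1.15 and the bicarbonate transporter gene Slc4a4 by 1.13. A second probe set of Retreg1 differed by 0.32. Of these 14 genes, Chac1 was lost from the calls without transgenic replicate 1, transgenic replicate 2 or wild-type replicate 3 (highest limma adjusted p = 0.0761), and the other 13 passed with any 1 array left out.

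More genes fell than rose by at least 1 log2 unit. Ankrd66 fell by 3.08 ± 0.12 (SE), an 8.48-fold difference, and the vesicle fusion gene Stx11 changed by -3.00 ± 0.14, the ubiquitin ligase gene Rnf180 by -2.82 ± 0.12 and Tecrl by -2.77 ± 0.10 (n = 3 each; limma adjusted p from 3.78e-05 to 6.59e-05). In transgenic lenses Ankrd66 stood at a mean of 4.37 and Tecrl at 4.59. Both lay near the arrays' lower quartiles of 4.1 to 4.2, so background may limit their folds. Ermap changed by -2.52, Sh3bgr by -2.52, the synaptic adhesion gene Lrrtm2 by -2.49 and the calcium-binding protein gene Cabp5 by -2.44. The stress-induced chromatin gene Nupr1 changed by -2.35, Hmox1 by -2.24, the unconventional myosin gene Myo7b by -2.23 and Dnase2b by -2.22. Gadd45b, a gene induced by growth arrest and DNA damage, changed by -2.14, and the cation channel gene Trpc6 by -2.11. The same limit holds for Lrrtm2 and Trpc6, at means of 4.33 and 4.41 in transgenic lenses. Of 2 further probe sets of Gadd45b, the dimmer differed by -0.69. Each of these 14 falls passed the test with any 1 array left out. Uox, next to Dnase2b in the RefSeq annotation of GRCm38.p6 and outside the rule for named genes, was also lower, at -1.86 ± 0.20 (SE; limma adjusted p = 0.00280).

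**Figure D2:**
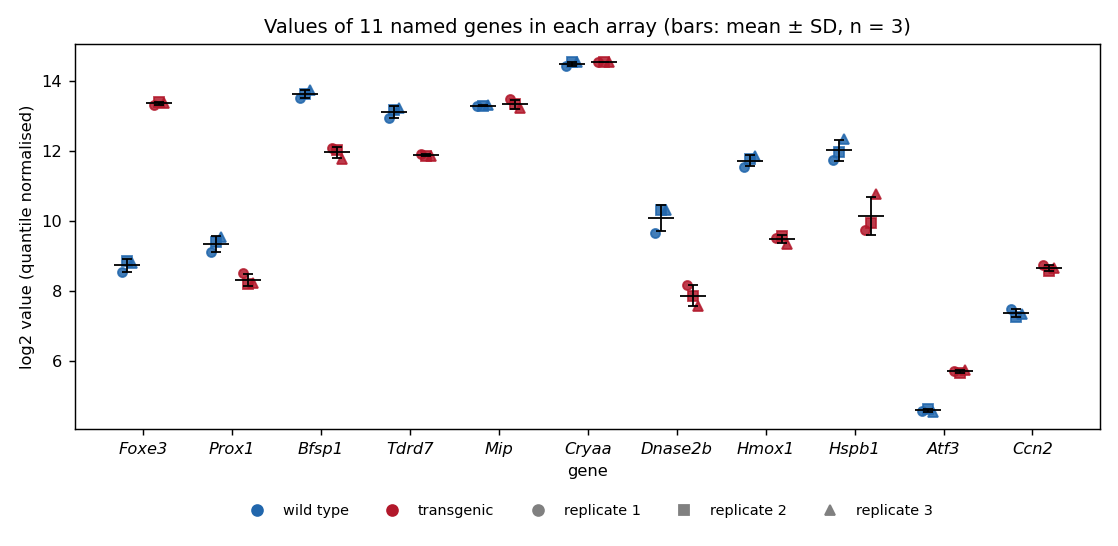
Log2 values of 11 named genes in each of the 6 arrays, with symbols for the replicates, colours for the genotypes and bars for the mean ± SD of 3 arrays. The groups lie apart for Foxe3, Prox1, Bfsp1, Tdrd7, Dnase2b, Hmox1, Hspb1, Atf3 and Ccn2, and overlap for Mip and Cryaa.

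Genes of lens fiber differentiation moved downward in part. Of 19 measured genes for fiber membrane, junction and beaded filament proteins, 7 fell, none rose and 12 did not pass (adjusted over the list alone, 10 fell). Bfsp1 changed by -1.66 ± 0.11 (SE), the apoptosis inhibitor gene Birc7 by -1.61, the RNA granule gene Tdrd7 by -1.23, the RNA-binding protein gene Caprin2 by -0.79, the chloride channel gene Clic5 by -0.74 and the adhesion gene Nrcam by -0.70. Mip, which encodes the fiber water channel, stood at 13.35 ± 0.13 and 13.31 ± 0.02 (SD, n = 3), a difference of 0.043 that did not pass. The list passed camera (limma, adjusted p = 4.13e-06), and had an adjusted p = 0.651 with an estimated correlation and 0.0324 in fry. Of the 19 genes, 6 fell without T1 or T3, 4 without T2 or W3, 3 without W2 and 9 without W1. On the values as deposited 8 fell, and after centring on a common median 10 did. Calls lost with 1 array left out, with the highest limma adjusted p, were those of Caprin2 (T2, W2 or W3, 0.0794), Clic5 (T2, W1, W2 or W3, 0.0903) and Nrcam (W2, 0.0528).

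Among 20 genes of organelle loss and terminal fiber differentiation, 4 fell and 16 did not pass (adjusted over the list alone, 5 fell and 1 rose). The calls were Hmox1, Dnase2b, the phospholipase gene Plaat3, which fell by 0.88, and the lipoxygenase gene Alox15, which fell by 0.70. Bnip3, at 0.43, and Uchl1, at -0.34, did not pass. The list's camera adjusted p was 0.0415 in limma, and the adjusted p = 0.651 with an estimated correlation. In fry it was 0.0324. The camera value was 0.0730 without transgenic replicate 1, 0.0824 without transgenic replicate 2 and 0.0568 without wild-type replicate 2, within a range of 0.00489 to 0.0824 over the 6 arrays left out. The call was also lost with dim probe sets left out (0.122) and with every probe set tested on its own (0.223). It was lost as well with the neural retina score as a covariate (0.0914) and with the replicate block, whose value is given with the settings below. The settings that kept all arrays and the preset correlation gave 0.0158 to 0.223. Alox15 lost its call with 1 array left out in 5 cases (T1, T2, T3, W2 or W3, adjusted p up to 0.129). The list's median was -0.072 and its mean -0.31. With 1 array left out the median ran from -0.12 (without T3) to -0.0099 (without T2), and after centring on a common median it was -0.16.

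Of 14 crystallin genes, Crygf fell by 0.73 ± 0.10 (SE; limma adjusted p = 0.00947) and 13 did not pass, with the same count adjusted over the list alone. Crygf was just short of the threshold without wild-type replicate 2 (limma adjusted p = 0.0528) or wild-type replicate 3 (0.0503). It has a single probe set here, and the crystallin genes Crygc and Cryge were not measured as single genes. Whether related transcripts share its signal was not tested. Cryaa differed by 0.034, Cryab by 0.031, Cryba1 by 0.052, Crygs by -0.064, Crygd by -0.10, Crygb by -0.13 and Crygn by -0.17. The sign of Cryab turned to -0.052 on the values as deposited and to -0.088 after centring on a common median. All 14 crystallins were among the 20 brightest genes. Their values reached 14.59, near the highest deposited values of the arrays, 14.7 to 14.8, where a change may be hard to see. Crygf, with a mean of 13.60, was the dimmest of the 14. The test therefore does not show that the other 13 were unchanged. In 6 of the crystallins the normalised values were identical in all 3 arrays of a group. The list did not pass camera (limma, adjusted p = 0.298, and adjusted p = 0.677 with an estimated correlation), and passed fry (adjusted p = 0.0445), which these tied values limit, with a median difference of -0.023.

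Of 27 lens transcription factor genes, Foxe3 rose, 2 fell and 24 did not pass; adjusted over the list alone, 3 rose and 3 fell. Prox1, which encodes a homeobox factor of fiber differentiation, changed by -1.04 ± 0.14 (SE; limma adjusted p = 0.00797), and the chromatin protein gene Hmgn3 by -0.64. Other probe sets of Prox1 differed by -0.33 and -0.68. Prox1 passed with any 1 array left out but lost its call in 3 of the other settings. The call was lost for Hmgn3 (T2, W2 or W3, 0.0741) with 1 array left out. The differences of Pax6 (-0.22), Sox1 (0.021), Sox2 (-0.54), Pitx3 (0.17), Hsf4 (-0.20), Rarb (0.45), Mafk (0.39) and Eya1 (-0.51) did not pass. A second probe set of Sox1 differed by -0.44. The brightest probe set of Maf differed by -0.062, while other probe sets of the gene differed by -0.98, -0.99, -1.07, -0.24 and -0.077. Of 25 lens epithelium genes, Foxe3 rose and 24 did not pass, with the same count adjusted over the list alone. Without W1, 2 genes of this list rose. Dkk3 (-0.31), Clu (0.23), Gja1 (0.52) and Abcb4 (0.18) did not pass. Neither list passed camera (limma, adjusted p = 0.127 for transcription factors and 0.905 for epithelium). In fry the epithelium list, with Foxe3 in it, passed (adjusted p = 0.0324) and the transcription factor list did not (0.406). The transcription factor list passed downward without transgenic replicate 2 (0.0467, within 0.0467 to 0.444 over the arrays left out), on the values as deposited (0.0246), after centring on a common median (0.0418) and with every probe set tested on its own (0.00213).

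**Figure D3:**
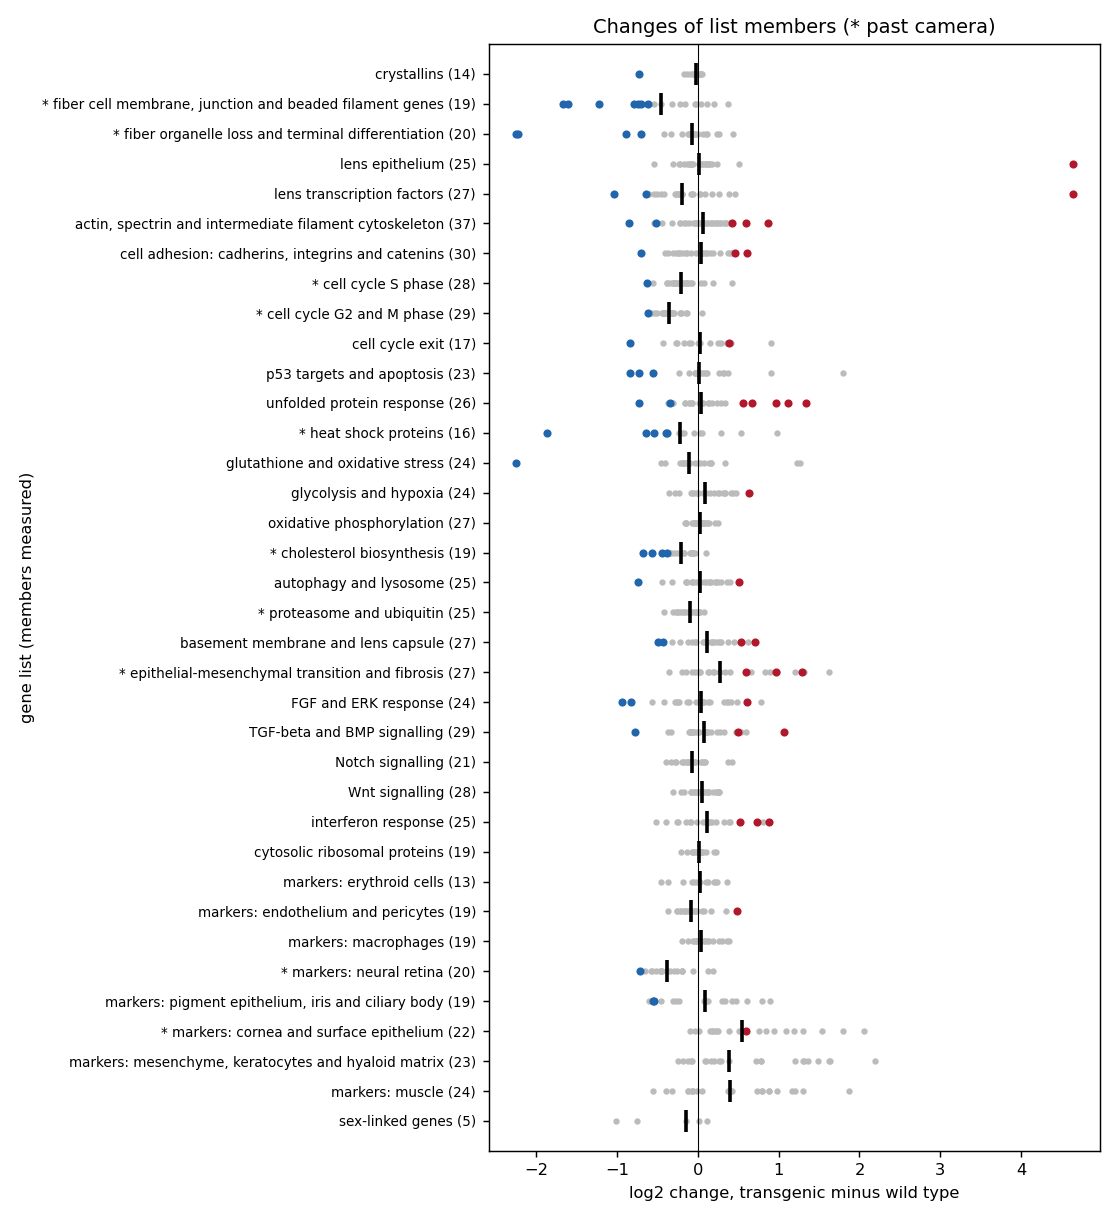
Log2 change (transgenic minus wild type) of each measured member of the 36 gene lists, red for higher, blue for lower and grey for not past limma's threshold; black bars are list medians and asterisks mark the 10 lists past camera with a preset correlation. The fiber membrane list has 7 lower members and a median of -0.45, and 28 of 29 genes of the G2 and M phase list lie below 0.

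Cytoskeletal, matrix and adhesion genes went both ways. Of 37 genes for actin, spectrin and intermediate filament proteins, 3 rose and 2 fell (adjusted over the list alone, 5 rose and 4 fell). The actin-binding protein gene Cald1 rose by 0.87 and the intermediate filament gene Vim by 0.60, while the spectrin gene Sptbn1 fell by 0.85 and Tmod2, encoding a protein that caps actin filaments, by 0.51. Of 27 basement membrane and lens capsule genes, 2 rose and 2 fell (adjusted over the list alone, 3 rose and 2 fell). The perlecan gene Hspg2 rose by 0.71 and the laminin gene Lama5 by 0.53, and the collagen-modifying enzyme gene P4ha2 fell by 0.49 and the laminin gene Lamb2 by 0.43. Of 30 adhesion genes, 2 rose and 1 fell (adjusted over the list alone, 3 rose and 3 fell). The integrin gene Itga6 rose by 0.61, the cadherin gene Cdh4 rose by 0.46 and Nrcam fell. None of the 3 lists passed camera (limma, adjusted p from 0.171 to 0.926), and the basement membrane list alone passed fry (adjusted p = 0.0445). Other probe sets differed by 0.16 for Cald1, 0.14 for Hspg2 and 0.23 for Lama5. The adhesion list had 0 risers without T1, T2, T3, W1 or W2 and 1 without W3, and 0 falls without W2. On the values as deposited 1 of its genes rose and 2 fell, and after centring 1 rose and 3 fell. The basement membrane list had 0 rises and 0 falls without T1, T2, W2 or W3, 1 rise without W1, and 2 rises and 0 falls without T3. After centring it had 1 rise. The cytoskeleton list had 1 rise and 1 fall without W2, and 1 fall without T2, T3 or W3. Calls lost with 1 array left out, with the highest limma adjusted p, were those of Tmod2 (T2, T3, W1, W2 or W3, 0.114), Vim (W2, 0.0541), Hspg2 (T1, T2, W2 or W3, 0.0957), Lama5 (T1, T2, W1, W2 or W3, 0.108), P4ha2 (any array, 0.117), Lamb2 (any array, 0.132), Itga6 (T1, T2, T3, W1 or W2, 0.112), Cdh4 (any array, 0.142) and Nrcam (W2, 0.0528).

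Of 27 genes of epithelial-mesenchymal transition and fibrosis, 3 rose and 24 did not pass, with the same count adjusted over the list alone. The risers were Ccn2, the smooth muscle actin gene Acta2 (0.97 ± 0.15, SE) and Vim. The list passed camera upward (limma, adjusted p = 0.0189, and adjusted p = 0.677 with an estimated correlation), and did not pass fry (0.295). Without transgenic replicate 3, the array with skin and muscle transcripts, the same test gave 0.747, and without wild-type replicate 2 it gave 0.0577, within a range of 0.000748 to 0.747 over the arrays left out. With the neural retina score as a covariate it gave 0.0505. Ccn2, Acta2 and Vim still rose without transgenic replicate 3, as 3 of the 27 members did. Calls were lost for Acta2 (T2, W2 or W3, 0.0685) and Vim (W2, 0.0541) with 1 array left out.

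Cell cycle lists passed camera downward in transgenic lenses, with few single genes past the test, but had an adjusted p = 0.677 with an estimated correlation and did not pass fry (limma, adjusted p = 0.163 for G2 and M phase and 0.284 for S phase). Of 29 genes of the G2 and M phases, the mitotic kinase gene Aurka fell by 0.62 ± 0.12 (SE; limma adjusted p = 0.0326) and 28 did not pass, although 28 of the 29 differences were below 0, with a median of -0.36. Adjusted over the list alone, 7 fell. Plk1 (-0.38), Tpx2 (-0.51) and Cenpe (-0.43) were below 0 without passing over all genes, and other probe sets of Tpx2 differed by -0.18, 0.56 and 0.33. Of 28 S phase genes, the thymidylate synthase gene Tyms fell by 0.63 and 27 did not pass (adjusted over the list alone, 1 fell). Tyms stood at 4.53 in transgenic and 5.17 in wild-type lenses. Both means lay under the median of all probe sets, 5.34, so background may blur its fall. Ccne1 (-0.31), Tk1 (-0.38) and Orc1 (0.42) did not pass. Camera gave a limma adjusted p = 3.99e-08 for G2 and M phase and 0.00139 for S phase, against an adjusted p = 0.677 with an estimated correlation for both. After centring on a common median, 2 genes fell in each list. Calls were lost for Aurka (T1, T2, W1, W2 or W3, 0.103) and Tyms (T2, T3, W1, W2 or W3, 0.118) with 1 array left out. The S phase list did not pass without transgenic replicate 1 (0.0619) or wild-type replicate 1 (0.0765), within a range of 6.53e-05 to 0.0765 over the arrays left out. Neural retina markers moved with these lists: 18 of the 20 were below 0 with a median of -0.38. With 1 array left out that median ran from -0.61 (without W3) to -0.23 (without T1).

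Of 17 genes of cell cycle exit, Cdkn1c, encoding an inhibitor of cyclin-dependent kinases, rose by 0.39 and Ccng1 fell by 0.83 (adjusted over the list alone, 3 rose and 2 fell). Ccnd3 (0.36) and Cdkn2c (-0.43) did not pass. Of 23 p53 target and apoptosis genes, 3 fell and 20 did not pass (adjusted over the list alone, 3 fell and 1 rose). The falls were Ccng1, Pmaip1, which encodes the death-promoting protein Noxa and fell by 0.72, and the death receptor gene Fas, which fell by 0.55. Pmaip1 stood at 3.88 in transgenic and 4.60 in wild-type lenses. Both means lay under the median of all probe sets, 5.34, so its fall may lie within background. Perp, at 1.80, did not pass, but without T3, where it stood highest, it rose by 1.16 (limma adjusted p = 0.00910, within 0.00910 to 0.199 over the arrays left out) and was the 1 riser of the list beside 2 falls. Calls were lost for Cdkn1c (any array, 0.124), Pmaip1 (T1, T2, W1, W2 or W3, 0.0981) and Fas (any array, 0.129) with 1 array left out. Neither list passed camera (limma, adjusted p = 0.763 and 0.917).

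Stress response genes were called in both directions. Of 26 genes of the unfolded protein response, 5 rose, 2 fell and 19 did not pass (adjusted over the list alone, 6 rose and 3 fell). The transcription factor gene Atf3 rose by 1.11 ± 0.08 (SE), Ddit3, which encodes the factor CHOP, by 0.97 ± 0.10, Trib3 by 0.67 and Chac1 by 1.34. The list did not pass camera (limma, adjusted p = 0.597) but passed fry (0.0445). A second probe set of Trib3 differed by 0.25. Of these genes, 3 rose without T1, T2 or W2, 2 without W3, 4 without T3 and 6 without W1. Falls numbered 1 without T1, T3 or W1 and 0 without T2, W2 or W3. Of 16 heat shock protein genes, 5 fell and 11 did not pass (adjusted over the list alone, 7 fell and 1 rose). Hspb1 changed by -1.86 ± 0.27 (SE; limma adjusted p = 0.0109), Hsph1 by -0.64, the mitochondrial co-chaperone gene Hspe1 by -0.54 and Hsp90aa1 by -0.38. Camera gave a limma adjusted p = 0.00441, and the adjusted p = 0.651 with an estimated correlation and 0.0324 in fry. Another probe set of Hsp90aa1 differed by -0.12. Of the heat shock genes, 3 fell without T1, T3 or W1, 1 without T2 or W2, and 0 without W3. Calls lost with 1 array left out, with the highest limma adjusted p, were those of Trib3 (W2 or W3, 0.0737), Chac1 (T1, T2 or W3, 0.0761), Hspb1 (T2, W2 or W3, 0.0537), Hsph1 (W3, 0.0506), Hspe1 (T2, W2 or W3, 0.0805) and Hsp90aa1 (any array, 0.12). Of 24 glutathione and oxidative stress genes, Hmox1 fell and 23 did not pass (adjusted over the list alone, 2 fell), Gss (-0.45) and Gclc (-0.41) among them (camera, adjusted p = 0.206, and 0.0324 in fry).

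Of 19 cholesterol synthesis genes, 4 fell and 15 did not pass, and 18 of the 19 differences were below 0 (adjusted over the list alone, 8 fell). Dhcr7, for the last step of the pathway, changed by -0.67, Cyp51 by -0.56, the squalene synthase gene Fdft1 by -0.45 and Pmvk by -0.38. Of 3 other probe sets of Fdft1, 1 fell alike (-0.42) and 2 dimmer ones went the other way (0.19 and 0.36). Of the 19, 1 fell without T1 or W1, and 0 without T2, W2 or W3, while 6 fell on the values as deposited and 7 after centring on a common median. Calls lost with 1 array left out, with the highest limma adjusted p, were those of Cyp51 (T2, W2 or W3, 0.059), Dhcr7 (T1, T2, W1, W2 or W3, 0.146), Fdft1 (T1, T2, W1, W2 or W3, 0.156) and Pmvk (any array, 0.154). Camera gave a limma adjusted p = 0.000101, and the adjusted p = 0.651 with an estimated correlation and 0.0445 in fry. No proteasome gene passed among 25, also when adjusted over the list alone, although 20 were below 0 and the list passed camera (limma, adjusted p = 0.0184, and adjusted p = 0.656 with an estimated correlation and 0.0445 in fry). Psmc1 (-0.42) and Psmb5 (-0.31) came nearest. Without transgenic replicate 2 the proteasome list gave 0.0824, within a range of 0.00947 to 0.0824 over the arrays left out, and with every probe set tested on its own 0.223. Of 24 glycolysis and hypoxia genes, the phosphoglycerate kinase gene Pgk1 rose by 0.63 and 23 did not pass (adjusted over the list alone, 5 rose and 1 fell). Its adjusted p was 0.0324 in fry and 0.0654 in camera, and in camera 0.0358 without transgenic replicate 3 or 0.0499 without wild-type replicate 1, within a range of 0.0358 to 0.117 over the arrays left out. It passed upward with dim probe sets left out (0.0372), with every probe set (0.00928), with trended robust variances (0.0314) and with array weights (0.0360). Of 25 autophagy and lysosome genes, the cargo receptor gene Sqstm1 rose by 0.50 and the protease gene Lgmn fell by 0.74 (adjusted over the list alone, 3 rose and 2 fell; camera, adjusted p = 0.499). The call was lost for Sqstm1 (any array, 0.112) with 1 array left out. None of 27 oxidative phosphorylation genes and none of 19 ribosomal protein genes passed in limma, over all genes or adjusted over the list alone (camera, adjusted p = 0.763 and 0.949).

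Signalling genes changed singly, and no signalling list passed camera (limma, adjusted p from 0.124 to 0.897). Of 24 genes of FGF signalling and the ERK response, the phosphatase gene Dusp4 fell by 0.93 and Fgf12 by 0.82, and the receptor gene Fgfr2 rose by 0.61 (adjusted over the list alone, 4 rose and 3 fell). Spry1, at -0.57, did not pass. The median of this list was 0.045 and its mean -0.0076, and camera's direction was downward. Its median turned to -0.034 on the values as deposited and -0.070 after centring. Without T3 it was -0.058 and without W2 -0.0082. Of 29 TGF-beta and BMP genes, the ligand genes Tgfb3 and Inhbb rose by 1.07 and 0.50 and the signal transducer gene Smad1 fell by 0.77, with the same counts adjusted over the list alone. None of 21 Notch genes and none of 28 Wnt genes passed in limma by either adjustment, though 1 Notch gene rose without T3. Of 25 interferon response genes, 3 rose and 22 did not pass (adjusted over the list alone, 5 rose): the antigen-presenting class I genes H2-K1 by 0.88 and H2-D1 by 0.74, and the RNA sensor gene Oas2 by 0.53. Other probe sets above the median level differed by 0.12 to 0.28 for H2-K1, by -0.27 and by 0.27 to 0.53 for H2-D1, and by 0.061 for Inhbb. The interferon list's adjusted p was 0.0699 in fry and 0.124 in camera, and in camera 0.0499 without wild-type replicate 1, within 0.0499 to 0.315 over the arrays left out. It passed after centring on a common median (0.0418) and with every probe set tested on its own (0.0473). Calls lost with 1 array left out, with the highest limma adjusted p, were those of Fgfr2 (any array, 0.11), Inhbb (T1, T2, T3, W1 or W3, 0.133), H2-K1 (T1, T2, T3, W2 or W3, 0.102), H2-D1 (T2, W1, W2 or W3, 0.0904) and Oas2 (any array, 0.132).

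Markers of other eye and body tissues showed how far the dissected samples differed in content. Transgenic replicate 3 had list scores of 1.26 for cornea and surface epithelium, 0.91 for mesenchyme and 0.88 for muscle, where the other 5 arrays lay between -0.39 and -0.15. The keratin gene Krt1, taken from a list written after the arrays were compared, stood at 13.13 in that array, at 6.48 to 7.28 in the other transgenic arrays and at 8.96 in wild-type replicate 3. Of 22 cornea and surface epithelium genes, Epcam rose by 0.59 and 21 did not pass, with the same count adjusted over the list alone. The list passed camera upward (limma, adjusted p = 0.00998, and adjusted p = 0.724 with an estimated correlation), did not pass fry (0.474), and in camera gave 0.931 without transgenic replicate 3, within a range of 5.38e-05 to 0.931 over the arrays left out, and 0.0624 with array weights or 0.119 with the neural retina score as a covariate. None of 23 mesenchyme and none of 24 muscle genes passed in limma by either adjustment. The mesenchyme list gave a camera adjusted p of 0.106, and passed upward without transgenic replicate 1 (0.0117) or transgenic replicate 2 (0.0221), within 0.0117 to 0.803 over the arrays left out, and after centring on a common median (0.0373). The call was lost for Epcam (T2 or W3, 0.0608) with 1 array left out, and without T3 the surface epithelium list had 2 risers, Epcam and Perp (1.16). The muscle list gave 0.589, and passed downward without transgenic replicate 3 (0.00489), within a range of 0.00489 to 0.831 over the arrays left out.

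Of 20 neural retina markers, the neuronal RNA-binding protein gene Elavl4 fell by 0.72 and 19 did not pass, with the same count adjusted over the list alone. The list passed camera downward (limma, adjusted p = 0.000996, and adjusted p = 0.677 with an estimated correlation), and did not pass fry (0.295). Its scores overlapped between the genotypes, at -0.53, 0.10 and -0.23 in transgenic and 0.46, 0.26 and -0.17 in wild-type arrays. Tubb3 (-0.65), Gap43 (-0.52) and Rcvrn (-0.26) did not pass. Of 19 pigment epithelium, iris and ciliary body genes, Mitf fell by 0.56 and Foxc1 by 0.54, with the same count adjusted over the list alone. Of 19 endothelial and pericyte genes, the receptor gene Tek rose by 0.49, with the same count adjusted over the list alone; the list passed downward without wild-type replicate 2 (0.0206, within 0.0206 to 0.866 over the arrays left out). No gene passed in limma among 13 erythroid, 19 macrophage and 5 sex-linked genes by either adjustment. Camera passed none of these 5 last lists (limma, adjusted p from 0.499 to 0.907). Calls lost with 1 array left out, with the highest limma adjusted p, were those of Elavl4 (W2, 0.0605), Mitf (T1, W2 or W3, 0.0918), Foxc1 (T1, T2, T3, W2 or W3, 0.135) and Tek (T1, T2, W1, W2 or W3, 0.152). The Y-linked gene Eif2s3y was low in transgenic replicate 2, at 4.45, and stood at 6.90 to 7.28 in the other arrays.

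**Figure D4:**
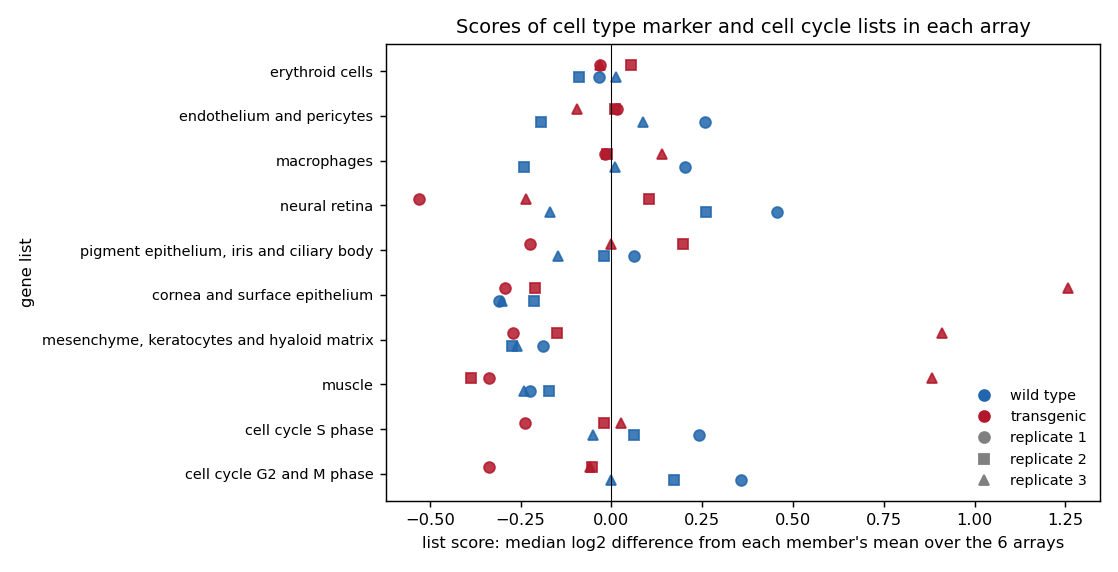
List scores of each array, the median over list members of the log2 difference from the member's mean over the 6 arrays, for cell type marker lists and cell cycle lists; colours are genotypes and symbols replicates. Transgenic replicate 3 lies apart at 1.26 for surface epithelium, 0.91 for mesenchyme and 0.88 for muscle, and neural retina and G2 and M phase scores are highest in wild-type replicate 1, at 0.46 and 0.36.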

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

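The tests of explanations in this part were chosen after the results they bear on were seen. Quantities outside the gene comparison showed a signal of their own. The bacterial hybridisation controls bioB, bioC and bioD, which are added in equal amounts to every hybridisation mix, were lower in transgenic arrays by a mean of -0.49 on the log2 scale, and all 14 of their probe sets lay below every wild-type array in all 3 transgenic arrays. With cre included, the mean was -0.42 over 18 probe sets, all lower, and the 4 of cre overlapped between the genotypes. These controls are not lens RNA, so their difference may stem from the handling or scaling of the arrays, which was not tested. It ran along with genotype, so its part in the gene calls cannot be told apart from genotype. The poly-A controls lys, phe, thr and trp, which are added to the RNA before labelling, differed by -0.074. Of their 21 probe sets, 4 lay below every wild-type array. Their means per array were 12.5 to 12.8, against 8.8 to 9.5 for bioB, bioC and bioD. So near the top of the range a difference may show less. Among probe sets without a gene name here, 47 passed the limma test (17 higher, 30 lower), and among those with several names 59 did (24 higher, 35 lower).

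Skin and muscle transcripts in transgenic replicate 3 drew attention because 39 of 69 members of the surface epithelium, muscle and mesenchyme lists lay at least 1 log2 unit above the other transgenic arrays, and none lay as far below. An effect of the transgene is argued against by the other 2 transgenic arrays, whose median difference from wild type over these members was -0.051 (quartiles -0.26 and 0.12), against a median of 1.31 in replicate 3. A wild-type sample under a transgenic label is argued against by Foxe3, at 13.39 in that array. Carried-over skin and muscle may be the source: among 31 cornified epidermis genes written down after the arrays were compared, 23 lay at least 1 log2 unit higher, with Krt10 at 13.55 and Krt1 at 13.13, while 0 of 71 erythroid, endothelial, macrophage and retina members did.

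The cell cycle and neural retina lists passed camera downward in transgenic arrays, but neither fry nor camera with an estimated correlation. The scores of the retina and the G2 and M phase lists correlated over the 6 arrays (Pearson's r = 0.937, exact permutation p = 0.00694; Spearman's rho = 0.943, exact permutation p = 0.0167; adjusted over the 3 relations tested, 0.0208 and 0.0250), r was 0.716 without the 2 arrays farthest from the median retina score, and within groups r was 0.917 (exact permutation p = 0.0833, adjusted 0.0833). With the retina score in the model, the group difference of the G2 and M score went from -0.33 (95% interval -0.71 to 0.06) to -0.13 (-0.39 to 0.13), so more neural retina in the wild-type samples may account for part of it and cannot be told apart from fewer dividing lens cells, since 6 arrays leave the interval wide. In camera with the preset correlation and the retina score as a covariate, the G2 and M list still passed downward (limma, adjusted p = 0.0253). The S phase list did not (0.603). A biological difference between the genotypes stays open, untested.

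Of 19 fiber membrane genes, 7 fell in transgenic arrays, and the list passed camera (limma, adjusted p = 4.13e-06, and adjusted p = 0.651 with an estimated correlation). A smaller share of lens RNA as the only cause is argued against by 8 fiber list members. They had wild-type means from 11 up to 13.64, the level of Bfsp1, which fell most among them. Their changes spread from -1.66 to 0.20, where dilution would lower all alike. The 95% intervals of 4 of the 8 excluded the median of these same members, -0.57. Different amounts of retina are argued against by the fiber list score, whose group difference was -0.47 (95% interval -0.71 to -0.22) and became -0.58 (-0.82 to -0.34) with the retina score in the model. An effect of the transgene on some late fiber genes stays a hypothesis from the same data.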

How the results depend on the processing

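The settings chosen after the data were seen were the retina score as a covariate and the list counts without transgenic replicate 3; the rest were planned. All 827 calls kept their direction on the values as deposited, after centring and with the retina score. With the mean of a gene's probe sets 823 of 827 did. With every probe set, direction was judged by the mean change over a gene's probe sets, so its 823 repeats that count. It does not show that each probe set went the same way. Other refits of the same values could not turn the sign of a call, since they kept its difference or its groups did not overlap. With 1 array left out the remaining arrays were normalised again, and all 827 calls kept their direction. Their groups did not overlap, so only the new normalization could have turned a sign. Every probe set on its own gave 580 higher and 905 lower, and array weights 599 and 790. The ordinary test gave 45 and 79, a log2 change of at least 1 as well 23 and 104, and the neural retina score as a covariate 56 and 204, with 5 gene lists. With 1 array left out the counts ran from 70 to 249 higher and from 153 to 390 lower, and 9 to 11 lists passed. With the replicate block they were 69 and 154, and the organelle loss list did not pass (0.0689); the same-numbered arrays' deviations correlated at -0.05, 0.08 and 0.03, transgenic replicate 1 did not correlate best with its own number, and the numbers were not taken to pair the samples. With an estimated inter-gene correlation 0 lists passed. Of 86 called genes named in the text, 56 lost their call in the ordinary test and 40 with the replicate block. With the retina score 37 did, with the mean of probe sets 17, and with array weights or trended robust variances 0. Among the genes named in the text, signs turned only for genes that had not passed. Sox1 became -0.056 on the values as deposited, -0.092 after centring, -0.21 with the mean of probe sets and -0.18 with the retina score. Cryab became -0.052 as deposited and -0.088 after centring. Mip became -0.0091 with the mean of probe sets and -0.0089 with the retina score. With 1 array left out, Sox1 ranged from -0.19 to 0.19, Maf from -0.21 to 0.052 and Mip from -0.024 to 0.11. The mean of probe sets gave 0.049 for Tpx2 and -0.0011 for Xist, and Xist ranged from -0.42 to 0.73 with 1 array left out, Krt1 from -0.67 to 2.65 and Krt10 from -0.33 to 2.12, lowest without transgenic replicate 3 for these 2 keratins. The cause was not tested. The pseudocount alternative was not run because the values were already on a log scale, and camera has no form for the ordinary test or the limit on size.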

Other observations

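The tests on splits of the arrays, on the rank of Foxe3 and on neighbouring genes were chosen after the results were seen. Sex-linked transcripts varied between the arrays. Xist, the noncoding RNA of the inactive X chromosome, stood at 11.08 in transgenic replicate 2, 8.77 in transgenic replicate 3 and 9.69 to 10.18 in the other 4 arrays. The Y-linked gene Kdm5d stood at 3.40 in transgenic replicate 2 and at 5.48 to 5.85 in the other arrays. Neither gene passed between the genotypes in limma. The 3′ minus 5′ difference of Gapdh probe sets was 0.030 to 0.075 in transgenic and -0.077 to 0.019 in wild-type arrays, which did not overlap. That of actin was 0.20 to 0.36 over all arrays, and the genotypes overlapped. The probe set at the 5′ end of 18S ribosomal RNA was highest in transgenic replicate 3, at 12.64, and wild-type replicate 1, at 12.37, and stood at 10.07 to 11.05 in the other arrays.

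With 10 ways to split the 6 arrays into 3 and 3, the share of splits can never be under 0.05. The real split called 827 genes in limma and the highest of the other 9 called 0, so 1 of the 10 splits gave as many.

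A hypothesis is that the transgene, which the labels do not name, carries Foxe3. It was prompted by the rank of Foxe3, which is 1 among 18193 genes by log2 rise (4.64, against 2.59 for Neat1), so that rank does not test it. Foxe3 may instead be induced from its own locus, which its single probe set, at one place in the transcript, cannot separate.

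A further hypothesis was that a stretch of another strain's DNA around the transgene lies behind a block of the calls. Called genes would then neighbour each other more often than shuffled calls. In the gene order of GRCm38.p6, 38 pairs of neighbouring genes were both called, and 10000 shuffles of the calls gave a mean of 37.6 (permutation p = 0.493). A single block of a few genes would be lost in this count over the whole genome, so the hypothesis stays open. Among calls of at least 1 log2 unit there were 2 such pairs, Dnase2b with Uox and Tnfrsf22 with Tnfrsf23, against 0.876 by chance (permutation p = 0.211).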
